A study of Mus musculus with 9 samples.

How the data were processed

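Single-cell RNA was measured with the 10x Genomics droplet assay in 7 kidney libraries from 4 lupus-prone mouse strains: 1 of B6.Sle1.Yaa, 3 of NZW/BXSB (2, 3 and 4), 1 of NZB/W and 2 of MRL/lpr (5 and 6). Per the labels' protocols, mice were perfused with saline, kidneys were digested with collagenase, and the cells were enriched with magnetic beads against CD11b and CD11c, or against CD45, before loading. Which of these beads was used for which library is not given in the sources used here. The B6.Sle1.Yaa and NZB/W libraries were hashed, which means that antibodies carrying a barcode (hashtags) marked the pool each cell came from.

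The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, for 27998 genes. Cell Ranger 6.0.1 and the mouse genome build mm10 are named in the submitters' processing notes, with no settings. The barcodes are a filtered set, per the labels of the matrix files. The deposited hashtag tables hold counts of 4 hashtags per barcode, and per the file headers a separate table names the pool behind each hashtag. Whether hashtag counts are reads or UMIs is not given in the sources used here. Of the gene identifiers, 27645 were matched to the GENCODE vM21 annotation of the same build, from which coordinates were taken, and 56 symbols that stand on more than 1 identifier were left apart by identifier.

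Everything else was computed from these counts. Cells with fewer than 500 UMIs, fewer than 300 genes or more than 10% mitochondrial UMIs were left out. Doublets were scored with Scrublet as built into scanpy 1.11.5, at an expected rate of 0.06. Its own threshold marked no cells in some libraries, so the highest-scoring 0.8% of barcodes per 1000 barcodes were removed, a rate chosen after that was seen. This removed between 4.6% and 17.4% of the cells of a library. Cells were scaled to 10000 UMIs and clustered library by library on 2000 variable genes, 30 principal components and 15 neighbours. Clustering used the igraph form of the Leiden algorithm in scanpy, at resolution 1. Clusters were named from marker lists fixed in advance, and a name needed at least 3 detected markers and a marker score at least 0.2 above that of the next class. The scoring thresholds were set after the clusters were seen. They left unnamed 1.58% of the cells in B6.Sle1.Yaa, 1.77% in NZB/W, 11.6% in MRL/lpr 5, 9.27% in MRL/lpr 6, 14.5% in NZW/BXSB 2, 12.2% in NZW/BXSB 3 and 4.31% in NZW/BXSB 4. All class names therefore mean clusters whose markers resemble that class.

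Hashtags were assigned with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99. It gave no hashtag to 51.8% of the NZB/W barcodes and 37.8% of the B6.Sle1.Yaa barcodes. UMI counts were then summed per library and class, or per hashtag and class, with at least 50 cells per library and 30 per hashtag. These sums are the replicates, and cells are not. Sums were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with its filter on low counts, TMM scaling and Benjamini-Hochberg adjustment at 0.05. Model types were compared with hashing as a covariate, and both hashed strains together with the library as a covariate. A log2 difference is the fitted one, with its standard error (SE), and levels are CPM (counts scaled to the same total for every sum) given as mean ± SD over the sums. For genes of the edgeR tests the totals were TMM-scaled. In the check of the labels, in summed lists and in 1 sum against 1 they were not, so 2 values of a gene can differ slightly. Within 1 hashed strain, 2 sick hashtags were compared with 1 young hashtag, so the spread rests on the sick pair alone.

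Of the 22 lists of genes fixed in advance, 21 had at least 3 measured genes in 1 or more comparisons and were tested there with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated as a check, and with fry, which asks whether a list moves on balance 1 way. The lists are interferon-stimulated genes, interferon-gamma and antigen presentation, lysosome and lipid-associated macrophage genes, complement, inflammatory cytokines and chemokines, the endosomal Toll-like receptor pathway, the Yaa translocated interval, the neighbours of the Sle1 interval, matrix remodelling and repair, scavenger and Fc receptors, kidney-resident macrophage genes, monocyte and recruitment genes, glycolysis and hypoxia, oxidative phosphorylation, immediate early and dissociation stress genes, cell cycle, sex-linked genes and the RNA of kidney tubule, neutrophils, immunoglobulin, haemoglobin and mitochondria. The immunoglobulin list held 1 measured gene and is given only as a sum. Shares of classes were compared with exact permutation tests, 2-sided. Where a class reached the minimum in only 1 sum per side there was no test. Both values are then given with exact Poisson intervals at 95%, which cover counting error only, and the 5 genes with the largest ratio in each direction are named, among genes with at least 4 counts per side and a mean of at least 50 CPM. List medians are placed among 10000 random lists of the same size and expression.

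Named genes follow a rule fixed before the data were examined. It takes the label check genes (Tlr7, Tlr8, Tmsb4x, Rab9, Xist, Ddx3y, Eif2s3y and Fas), up to 4 members of each list with the smallest p, and the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the sides. Sex-linked, immunoglobulin, T cell receptor, haemoglobin, mitochondrial, ribosomal protein and unnamed predicted genes are left out of the last part. Genes named outside the rule are said to be so, and some genes that it takes are not reported here. The tests were checked on simulated counts with 200 genes changed. For macrophages by model type the test recovered 7.5% of genes changed by 1 on the log2 scale, 79.1% of those changed by 2 and 100% of those changed by 3. For macrophages by stage in both hashed strains it recovered 86.6% of those changed by 1.

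Before the data were examined, the design, the comparisons by model type, strain and stage, and most alternatives were fixed: RLE scaling, DESeq2 1.42.0, no filter on low counts, each library or hashtag left out, a mitochondrial limit of 20%, doublets kept, Leiden resolution 2, no covariate, 1 group per strain, strains summed, and other hashtag rules. Chosen after the data were seen were the comparison by stage in nonclassical monocytes, the comparison of kidney with blood, the rule for 1 sum against 1, and the alternatives that used a mixture rule for hashtags, kidney or sick hashtags only, clusters with a median of at least 1500 UMIs, NZW/BXSB 3 and 4 left out, 1 cluster per library, or at least 50 classical monocytes for Tlr7.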

Results

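The libraries hold myeloid and other immune cells of mouse strains used as models of lupus nephritis, an inflammation of the kidney driven by deposited immune complexes. The cells are labelled as kidney, apart from 2 blood hashtags. The Tlr7-overexpression model type was represented by 4 libraries from males, 1 of B6.Sle1.Yaa and 3 of NZW/BXSB (2, 3 and 4). These males carry the Yaa translocation, an extra copy on the Y chromosome of an X-linked segment that holds Tlr7, an endosomal receptor for single-stranded RNA. The lymphoid-expansion model type was represented by 3 libraries from females, 1 of NZB/W and 2 of MRL/lpr (5 and 6). In MRL/lpr the lpr allele disrupts Fas, a death receptor that limits lymphocyte numbers. Model type, sex and strain cannot be separated in this design. In the B6.Sle1.Yaa and NZB/W libraries, hashtags marked kidney cells of young mice (1 hashtag per library), kidney cells of sick mice (2 hashtags) and blood cells of sick mice (1 hashtag). Comparisons by model type used all cells of these libraries, young and blood cells included. The stage of the other 5 libraries is not in the labels. The names of the kidney hashtags carry different codes, and some join several codes, as a pool of several mice would, but the labels do not say what the codes mean. Nothing says that the unhashed libraries came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

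The libraries held between 5742 barcodes (NZW/BXSB 4) and 21711 (NZW/BXSB 2), of which 3923 to 17315 were kept. Total UMIs ranged from 12370019 in NZW/BXSB 4 to 142493664 in B6.Sle1.Yaa. The median per kept cell ranged from 1433 UMIs in NZW/BXSB 2 to 7141 in B6.Sle1.Yaa, with 2477 in NZB/W, 3860 in MRL/lpr 5, 3655 in MRL/lpr 6, 1820 in NZW/BXSB 3 and 1916 in NZW/BXSB 4. Hashtags were assigned to 1666 young kidney, 1458 and 1291 sick kidney and 1179 blood barcodes in NZB/W, and to 3438 young kidney, 1488 and 2834 sick kidney and 340 blood barcodes in B6.Sle1.Yaa.

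The sex-linked and translocated genes were examined first because they check the labels. Xist (chromosome X, 103460366 to 103483254), the RNA that silences 1 X chromosome in females, stood at 814 ± 443 CPM over all cells of the lymphoid-expansion libraries (SD, n = 3) and at 0.0817 ± 0.0549 in the Tlr7-overexpression libraries (SD, n = 4). The Y-linked Ddx3y (Y, 1260771 to 1286629) and Eif2s3y (Y, 1010543 to 1028847) stood at 63.7 ± 14.8 and 59.4 ± 9.24 CPM in the Tlr7-overexpression libraries and at 0 in each lymphoid-expansion library, where 3 counts would be 0.0841 to 0.114 CPM. For these 3 genes the exact permutation p was 0.0286 (2-sided), the smallest that 35 splits allow. Tlr7 (X, 167304929 to 167330558) stood at 81.9 ± 21.7 against 33.7 ± 20.9 CPM, a log2 ratio of 1.28, but the groups overlapped, since NZW/BXSB 3 at 54.0 CPM lay below NZB/W at 57.6 (exact permutation p = 0.0857). Its neighbour Tlr8 (X, 167242696 to 167264329), another endosomal RNA receptor, stood at 29.3 ± 12.5 against 5.84 ± 0.71 CPM with no overlap between all 7 libraries (exact permutation p = 0.0571). In macrophages alone the log2 ratio of Tlr7 was 0.79, with 92.1 ± 27.7 against 53.5 ± 6.19 CPM (n = 3 each, exact permutation p = 0.10, the smallest possible). In classical monocytes it was 0.23 with NZW/BXSB 4, which gave 20 such cells, and 0.055 over the libraries with at least 50. There the difference fitted with hashing as a covariate was -0.18. Of the other genes on the translocated segment, Tmsb4x stood at 24180 against 14710 CPM (exact permutation p = 0.20) and Rab9 at 46.1 against 33.4 (exact permutation p = 0.0857). Fas was lower on average in the Tlr7-overexpression libraries, at 26.8 ± 5.38 against 41.4 ± 16 CPM (exact permutation p = 0.0857). Its level in MRL/lpr 5 and 6 was 30.0 and 59.7 CPM, and 3' counts do not show the structure of the lpr transcript. Adjusted over these 8 genes, the permutation p was 0.0762 for Xist, Ddx3y and Eif2s3y, 0.098 for Tlr7, Tlr8, Rab9 and Fas, and 0.20 for Tmsb4x.

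**Figure D1:**
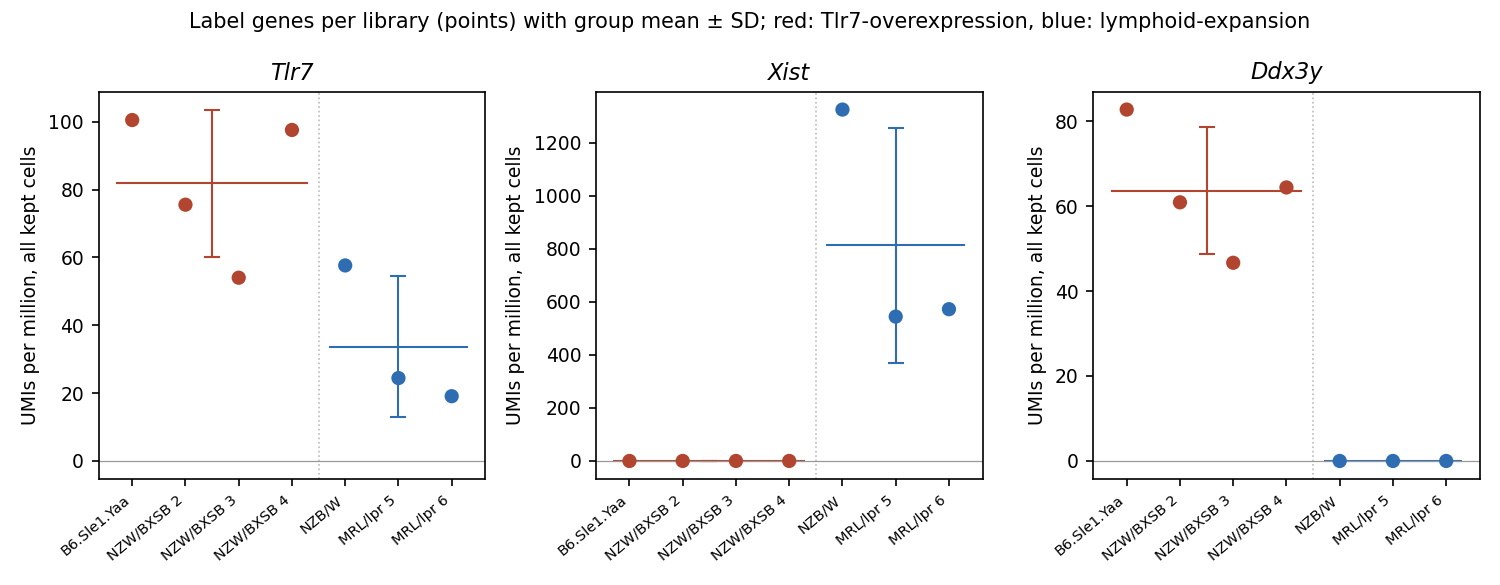
Tlr7, Xist and Ddx3y in each of the 7 libraries, in CPM over all kept cells (points), with the mean and SD of each model type. Xist separates the female from the male libraries and Ddx3y the reverse, whereas Tlr7 overlaps, with NZW/BXSB 3 at 54.0 below NZB/W at 57.6.

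Macrophages and nonclassical monocytes made up most of the cells in the hashed libraries. Lymphocytes made up much of the others except NZW/BXSB 4. There 65.9% of the cells were nonclassical monocytes, 7.80% T cells and 2.27% NK cells, and 433 of 3923 were B cells. Macrophages (C1qa, C1qb, Adgre1) were 45.7% of the cells in B6.Sle1.Yaa, 39.2% in NZB/W, 33.6% in MRL/lpr 5, 11.8% in MRL/lpr 6, 9.12% in NZW/BXSB 2 and 1.28% in NZW/BXSB 3, and no cluster of NZW/BXSB 4 was named so. Nonclassical monocytes (Ace, Treml4, Spn), which patrol vessel walls, were 65.9% in NZW/BXSB 4 and 30.4% in B6.Sle1.Yaa, and averaged 32.6 ± 24.8% against 9.93 ± 13.7% by model type (exact permutation p = 0.143). Macrophages averaged 14.0 ± 21.5% against 28.2 ± 14.4% (exact permutation p = 0.371), a difference of -14.2 points that became -0.76 without NZW/BXSB 3 and 4. B cells were 53.1% of NZW/BXSB 3, T cells were 53.0% of MRL/lpr 6, and neutrophils averaged 3.59 ± 1.85% against 0.945 ± 0.978% (exact permutation p = 0.114). None of the 16 classes passed after adjustment (adjusted p = 0.743 for macrophages, nonclassical monocytes and neutrophils), and the smallest p that the 35 splits allow was 0.0286. The bead selection can set these shares, and a class at 0 means only that no cluster of that library carried the name. RNA of other cell types also differed between libraries. Neutrophil RNA summed to 31360 CPM in NZW/BXSB 4, 25570 in NZW/BXSB 3 and 13460 in B6.Sle1.Yaa, but to 744 to 1682 CPM in the other 4. Immunoglobulin RNA, from a list with a single measured gene, stood at 17630 CPM in MRL/lpr 6 against 12.1 in B6.Sle1.Yaa. Haemoglobin RNA summed to 15960 CPM in NZW/BXSB 4 against 2.17 in MRL/lpr 5. Kidney tubule RNA ranged from 705 CPM in NZW/BXSB 3 to 1781 in B6.Sle1.Yaa. Napsa, which immune cells also express, gave 489.8 of the 705 CPM in NZW/BXSB 3 and 346 of 912 in NZW/BXSB 4.

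**Figure D2:**
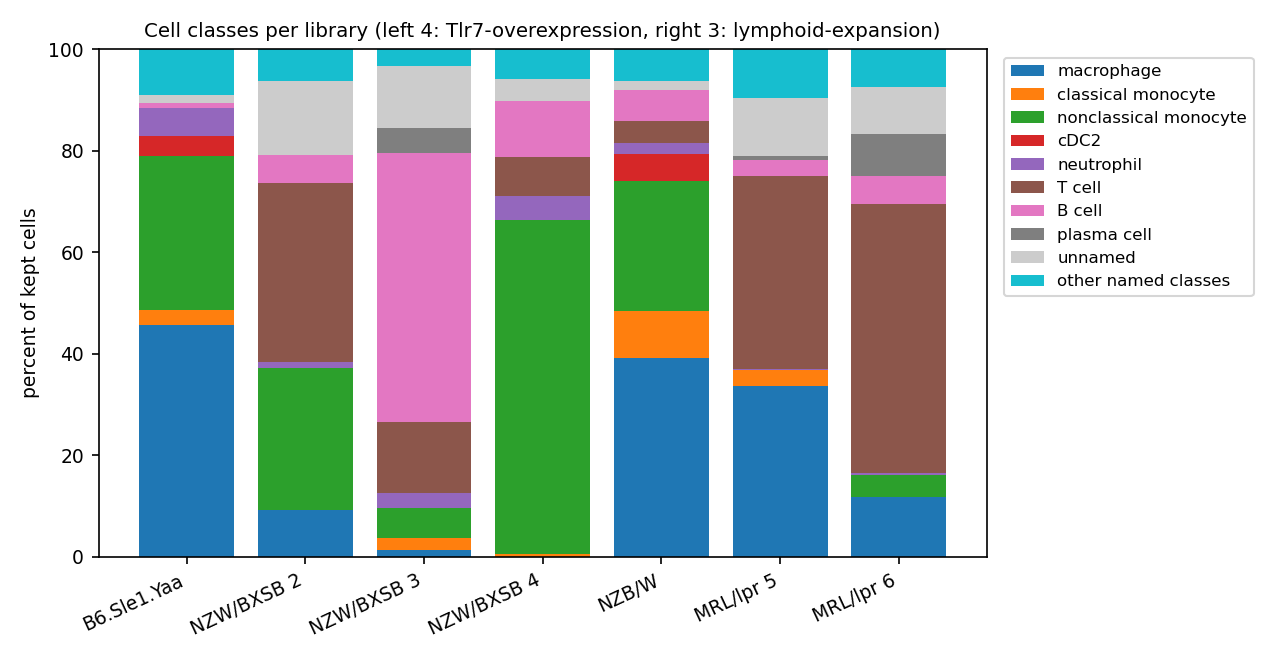
Shares of cell classes in percent of the kept cells of each library, as stacked bars. Macrophages take 45.7% of B6.Sle1.Yaa and 39.2% of NZB/W, nonclassical monocytes 65.9% of NZW/BXSB 4, and B cells 53.1% of NZW/BXSB 3.

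The first comparison asked which macrophage genes differ between the model types, with B6.Sle1.Yaa and NZW/BXSB 2 and 3 on 1 side and NZB/W and both MRL/lpr libraries on the other (n = 3 each). Beyond the genes of sex, the difference that passed was in Chil1 (chromosome 1, 134182176 to 134190181), a secreted chitinase-like protein made by activated macrophages, at 4.15 ± 1.81 CPM against 189 ± 147. Its log2 difference was -5.41 ± 0.52 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0416). Gm8909, a predicted gene named here after its values were seen, fell by 4.46 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0384). In T cells Gm8909 also differed between strains, at 919.1 CPM in MRL/lpr against 97.05 in NZW/BXSB, so its difference may be one of strain. The other genes past the threshold were Xist (0.0851 against 892 CPM), Ddx3y (51.3 ± 23.4 against 0 CPM), Eif2s3y (49.8 ± 12.6 against 0 CPM) and the Y-linked histone demethylase Kdm5d (16.6 against 0.0866 CPM). In all, 6 of 10973 genes passed, 3 higher and 3 lower, while 1882 had an unadjusted p under 0.05 and DESeq2 called 591. Of the 14 measured genes of the Yaa interval, 13 were higher in the Tlr7-overexpression libraries, 0 passed over all genes and 6 passed when adjusted over the list alone. Its camera adjusted p was 2.76e-05, with adjusted p = 0.163 with an estimated correlation, and fry gave 0.0345. Tlr8 showed a log2 difference of 2.07 ± 0.32 (63.0 against 16.2 CPM), Ofd1 of 1.36 ± 0.27 and Tlr7 of 0.70 ± 0.28 (90.0 ± 29.4 against 55.8 ± 10.3 CPM), none past the threshold. Of the 5 measured sex-linked genes, 3 rose and 1 fell, and all 5 passed over the list alone (camera adjusted p = 2.04e-13, adjusted p = 0.0845 with an estimated correlation).

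Genes of kidney-resident macrophages lay lower in the Tlr7-overexpression libraries. Of the 20 on that list, 19 were lower, with Cd81 at 761 against 1870 CPM and the microglia-type receptor Gpr34 at 13.8 against 65.8 CPM, but 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 5.29e-06, adjusted p = 0.602 with an estimated correlation). Macrophages of NZW/BXSB 3 stood apart here, with a mean log2(CPM + 1) over the list of 6.61 against 8.86 to 9.75 in the other 5 libraries. Inflammatory cytokines and chemokines were lower in 23 of 25 genes, scavenger and Fc receptors in 15 of 20 (Fcgr3, an activating IgG receptor, at 275 against 819 CPM), and interferon-gamma and antigen presentation genes in 23 of 29 (Cd74, the invariant chain of class II molecules, at 22980 against 59710 CPM). Immediate early and stress genes were lower in 14 of 18, with Dusp1 at 230 ± 47.2 against 873 ± 461 CPM. None of these genes passed over all genes, and adjusted over the list alone 1 stress gene passed. The camera adjusted p values were 0.00101, 0.00253, 0.00466 and 0.00431, and with an estimated correlation the adjusted p was 0.602 to 0.617. Moving with these groups, tubule RNA was lower in 15 of 19 genes (camera adjusted p = 0.000239), neutrophil RNA was higher in 10 of 10 (0.0149), mitochondrial RNA was higher in 12 of 13 (0.00253) and cell cycle genes were higher in 13 of 17 (0.0104, 1 passing adjusted over the list alone), at an adjusted p of 0.602 to 0.617 with an estimated correlation. Camera made no call for interferon-stimulated genes (14 of 28 higher, adjusted p = 0.386), lysosome and lipid-associated genes (19 of 28 lower, 0.0555), complement (11 of 16 lower, 1 passing adjusted over the list alone, 0.0887), the endosomal Toll-like receptor pathway (13 of 23 lower, 3 up and 1 down adjusted over the list alone, 0.412), the Sle1 neighbours (7 of 13 lower, 0.217), matrix remodelling (12 of 21 lower, 0.336), monocyte genes (13 of 18 higher, 0.328), glycolysis (13 of 19 lower, 0.204) or oxidative phosphorylation (13 of 20 lower, 0.386). Complement factor B (Cfb) stood at 12.2 against 96.9 CPM and the ribonuclease Rnaset2a at 46.3 against 306 CPM, both short of the threshold. The count of 6 genes became 20 without B6.Sle1.Yaa, 23 without NZB/W, 3 without MRL/lpr 5, 2 without MRL/lpr 6, 0 without NZW/BXSB 2 and 3 without NZW/BXSB 3. It was 3 with NZW/BXSB 3 and 4 left out, 3 without the covariate, 3 in clusters of at least 1500 median UMIs, 53 without the filter, 13 with 1 group per strain and 0 with strains summed.

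In classical monocytes (B6.Sle1.Yaa and NZW/BXSB 3 against NZB/W and MRL/lpr 5), no single gene passed edgeR's test among 9783, while 563 had an unadjusted p under 0.05 and DESeq2 called 83. All 20 kidney-resident macrophage genes were lower in the Tlr7-overexpression side, and 12 passed when adjusted over the list alone against 0 over all genes (camera adjusted p = 2.15e-30, adjusted p = 0.496 with an estimated correlation). Among them the complement component C1qc stood at 61.8 ± 56.4 against 603 ± 379 CPM. Cytokines were lower in 22 of 23 genes (8 over the list alone) and complement in 11 of 13 (6 over the list alone), with Cfb at 7.89 ± 3.39 against 62.1 ± 12.4 CPM. Lysosome genes were lower in 22 of 26 (5 over the list alone) and tubule RNA in 9 of 11 (4 over the list alone), and for these 4 lists the estimated correlation gave an adjusted p of 0.496 to 0.572. The fatty acid receptor Cd36 stood at 14.8 ± 11.4 against 218 ± 146 CPM and the lectin Mgl2 at 7.12 against 108 CPM. The Yaa interval was higher in 11 of 13 genes (camera adjusted p = 9.48e-05, adjusted p = 0.496 with an estimated correlation), although Tlr7 itself stood at 74.3 ± 60.7 against 70.2 ± 4.83 CPM. Cell cycle genes were higher in 16 of 17 (1 over the list alone, camera adjusted p = 1.89e-07, adjusted p = 0.626 with an estimated correlation). NZW/BXSB 3, whose macrophages stood apart, is 1 of the 2 libraries on the Tlr7-overexpression side, and MRL/lpr 5 over it alone had median log2 ratios of 2.62 for kidney-resident and -3.34 for cell cycle genes. The count of 0 became 122 without the filter, 29 with the mitochondrial limit at 20% and 5 at Leiden resolution 2.

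In nonclassical monocytes B6.Sle1.Yaa and NZW/BXSB 2, 3 and 4 were compared with NZB/W and MRL/lpr 6. NZW/BXSB 3 and 4 held little RNA of most kidney tubule genes. Over all cells Fxyd2 stood there at 0.326 and 0.501 CPM, against at least 34.7 in the other 5 libraries. A difference of tissue can therefore not be told from one of model type here. Of 11256 genes, 23 passed, 15 higher and 8 lower in the Tlr7-overexpression libraries, with 1337 at an unadjusted p under 0.05 and 304 by DESeq2. On the list of sex-linked genes were 4 of the higher and 2 of the lower. Fcrl5 (chromosome 3, 87435773 to 87500678), an Fc receptor-like protein best known from B cells, rose to 223 ± 76.1 from 17.3 ± 11 CPM, a log2 difference of 3.48 ± 0.29 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00382). The integrin Itgad rose to 63.0 ± 19.7 from 0.904 ± 1.08 CPM (log2 difference 6.80 ± 0.61; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00521), and Nxpe4 to 70.2 ± 51.0 from 2.56 ± 2.44. Trim12a (38.8 against 2.35 CPM) and Trim5 (12.6 against 0.138 CPM), members of an antiviral family, rose, as did Ifit1bl1 of an interferon-induced family (50.8 against 1.24 CPM). The cell cycle inhibitor Cdkn2a rose (17.5 against 0.345 CPM), together with the transcription factor Sox5 (log2 difference 3.80), Lysmd2 (3.69) and the ubiquitin ligase Rnf144a (2.42). Trim12a and Trim5 lie among closely related copies, so their counts are uncertain. Trim12a also differed between strains in T cells, at 0.108 CPM in MRL/lpr against 51.25 in NZW/BXSB. Its difference is thus not particular to this class and may be one of strain. Cfb fell by 2.58 on the log2 scale, from 66.4 ± 22.9 to 11.1 ± 3.20 CPM, the arginine synthesis enzyme Ass1, which is also on the tubule list, fell by 2.27, and Dusp6, a brake on ERK signalling, fell by 1.64.

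Among the groups in nonclassical monocytes, lysosome and lipid-associated genes were lower in 23 of 29, with 0 passing over all genes and 1 rising and 7 falling when adjusted over the list alone (camera adjusted p = 2.32e-06, adjusted p = 0.456 with an estimated correlation). Lpl, a lipoprotein lipase, stood at 94.9 ± 22.7 against 397 ± 99.3 CPM and lysozyme Lyz2 at 3465 against 10890 CPM, both short of the threshold. The Tlr7-overexpression side includes NZW/BXSB 3 and 4, which are low in kidney RNA. Scavenger and Fc receptors were lower in 17 of 20 (1 up and 3 down over the list alone, 0.00106 by camera, adjusted p = 0.456 with an estimated correlation). Within this list Fcgr3 stood at 113 ± 24.3 against 393 ± 100 CPM, but Fcgr4, another activating IgG receptor, at 1615 ± 207 against 764 ± 194 CPM. Cytokines were lower in 21 of 24 (0.000159 by camera), the Sle1 neighbours in 11 of 13 (1 up and 3 down over the list alone, 0.00186 by camera), and both these lists had an adjusted p of 0.456 with an estimated correlation. The Yaa interval was higher in 12 of 14 genes, with 0 passing over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000158, adjusted p = 0.257 with an estimated correlation, fry 0.0436). Tlr7 stood at 135 ± 21.9 against 94.8 ± 14.6 CPM and Tlr8 at 40.8 ± 11.8 against 11.8 ± 9.27 CPM. Mitochondrial RNA was higher in 12 of 13 genes (3 over the list alone, 5.64e-07 by camera, adjusted p = 0.456 with an estimated correlation), and haemoglobin RNA was lower in 3 of 4 without a call (camera adjusted p = 0.789). The count of 23 became 97 without B6.Sle1.Yaa (43 higher, 54 lower), 104 without MRL/lpr 6 (41 and 63), 117 without NZB/W (47 and 70), 11 without NZW/BXSB 3, 12 without NZW/BXSB 4 and 0 without both of the last. It was 109 with the mitochondrial limit at 20% (49 higher, 60 lower), so that genes lower in the Tlr7-overexpression libraries were the more numerous in these 4 fits. It was 8 without the covariate, 15 at Leiden resolution 2, 13 with sick hashtags only, 131 without the filter, 122 with 1 group per strain and 0 with strains summed.

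Conventional type 2 dendritic cells (cDC2), which present antigen to helper T cells, reached the minimum only in B6.Sle1.Yaa (5302554 UMIs) and NZB/W (2808850 UMIs), so the difference has no replicate check and no test was made. All intervals cover counting error only. B6.Sle1.Yaa held less Cd36, at 5.47 CPM (3.66 to 7.85) against 199 (183 to 216), less of the chemokine Ccl12, at 4.34 against 156 CPM, less Cd81, at 40.2 (35 to 45.9) against 900.0 (865 to 936), and less Tpm3-rs7 and Adap2os. It held more of the survival gene Bcl2a1d, at 224 CPM (211 to 237) against 14.2 (10.2 to 19.4), the mitochondrial tRNA ligase Lars2, at 135 against 3.56 CPM, AY036118, AA467197 and Ppfia4. Tlr7 stood at 8.11 CPM (5.87 to 10.9) in B6.Sle1.Yaa against 25.3 (19.7 to 31.9) in NZB/W. The median log2 ratio was -2.14 for the kidney-resident macrophage list and -1.58 for complement, each at percentile 0.0 of random matched lists, -1.32 for cytokines, -1.08 for scavenger and Fc receptors and 0.93 for mitochondrial RNA (percentile 99.9). With macrophage genes this far apart, the clusters named cDC2 may not hold the same mix of cells in both libraries. This was not tested and applies to Tlr7 too.

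Within the unhashed libraries, MRL/lpr (5 and 6) was compared with NZW/BXSB (2 and 3) in macrophages. Class I-like genes of the major histocompatibility complex separated the strains: H2-Q4 rose to 2734 ± 53.3 from 257 ± 45.0 CPM (log2 difference 3.41 ± 0.31; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0424), H2-Q1 to 767 ± 25.9 from 46.4 ± 14.7 CPM and H2-M2 to 236 ± 40.3 from 0.658 ± 0.930 CPM, while H2-Q6 fell by 3.66 on the log2 scale (7.04 against 90.8 CPM). The H2-Q genes among them are near-identical copies, so their single counts are uncertain. In all, 18 of 10678 genes passed, 10 higher and 8 lower in MRL/lpr, with 2350 at an unadjusted p under 0.05 and 461 by DESeq2. The MRL/lpr libraries came from females and the NZW/BXSB libraries from males, and 3 of the 18 were the sex-linked Xist, Ddx3y and Eif2s3y. The ADP-ribosyltransferase Art2b (49.0 against 0.263 CPM), the proton pump subunit Atp6v0e2 (21.7 against 0.132 CPM), the serine protease inhibitor Serpina3f (83.9 ± 2.83 against 3.40 ± 1.15 CPM) and the surface protein Ly6i (132 ± 5.26 against 8.07 ± 1.36 CPM) rose. The sialyltransferase St6galnac2 fell, at 0.289 against 79.0 ± 4.02 CPM, as did Rasal2 (1.72 against 29.2 CPM), Hist1h2al (0.0606 against 59.5 CPM) and Trim12a, which had no count in MRL/lpr against 29.7 ± 5.56 CPM.

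Interferon-gamma and antigen presentation genes were higher in MRL/lpr macrophages in 26 of 29, with 0 passing over all genes and 7 adjusted over the list alone (camera adjusted p = 1.51e-06, adjusted p = 0.389 with an estimated correlation). The chemokine Cxcl9 stood at 511 ± 53.6 against 52.0 ± 38.8 CPM, the GTPases Iigp1 at 59.4 against 13.8 and Gbp2 at 130 ± 22.9 against 48.5 ± 13.5, and H2-K1 at 4671 against 1868 CPM. Kidney-resident macrophage genes were higher in 19 of 20 and scavenger and Fc receptors in 18 of 21 (1 over the list alone), at camera adjusted p values of 6.05e-06 and 0.000497 and an adjusted p of 0.582 and 0.486 with an estimated correlation. In the kidney-resident list NZW/BXSB 3, 1 of the 2 NZW/BXSB libraries, stood apart, with a mean log2(CPM + 1) of 6.61 against 8.86 in NZW/BXSB 2 and 9.35 and 9.75 in MRL/lpr. Stress genes were higher in 16 of 18 (camera adjusted p = 0.000188, adjusted p = 0.582 with an estimated correlation), and tubule RNA in 14 of 18 (0.00348, adjusted p = 0.594 with an estimated correlation). Neutrophil RNA was lower in 9 of 10 (7 over the list alone, camera adjusted p = 4.11e-05) and cell cycle genes in 14 of 17 (7 over the list alone, 4.11e-05). For both the adjusted p was 0.582 with an estimated correlation. The Yaa interval was lower in 12 of 14 genes (1 over the list alone, camera adjusted p = 0.000497, adjusted p = 0.389 with an estimated correlation). The count of 18 became 379 without NZW/BXSB 2, 38 without NZW/BXSB 3 and 1649 without the filter.

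For classical monocytes only MRL/lpr 5 and NZW/BXSB 3 reached the minimum, so no test was made. NZW/BXSB 3 stood apart from the other libraries. Myeloid precursor genes summed over all its cells to 874.3 CPM, against 65.5 in MRL/lpr 5. The differences may thus belong to this library and not to the strain. Of the named genes lower in MRL/lpr 5, the protease Prtn3 stood at 13.6 CPM (8.53 to 20.6) against 2413 (2346 to 2481), S100a8 at 5.57 against 912, S100a9 at 6.18 against 813, Ctsg at 4.33 against 535 and Lcn2 at 3.09 against 297. The higher side held Hpgd, a prostaglandin-degrading enzyme, at 373 CPM (344 to 404) against 6.41 (3.41 to 11), Cxcl2, the heat shock gene Hspa1a, Mgl2 at 174 against 8.38 CPM and C1qb at 416 against 20.7 CPM. List medians were 2.62 for kidney-resident macrophage genes, 2.28 for stress genes and 2.18 for cytokines (each at percentile 100 of random lists) and -3.34 for cell cycle genes (percentile 0.0).

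The stage comparison asked how kidney macrophages of mice labelled sick differ from those of mice labelled young, first over both hashed strains (4 sick and 2 young hashtags). No hashtag names older mice without disease, so age and disease cannot be separated in any comparison by stage. Depth moved with stage too, since young macrophages held more UMIs per cell in both strains. The median was 4328 in young against 2956 and 2679 in sick NZB/W hashtags, and 12719 against 6595.5 and 7627 in B6.Sle1.Yaa. Its part in the stage differences of macrophages was not tested. Hmox1, F10 and Capg were among the genes that rose in sick kidneys, and Adrb1 and Scimp among those that fell. Heme oxygenase Hmox1 rose to 257 ± 81.4 from 107 ± 33.1 CPM (log2 difference 1.26 ± 0.18; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0191), coagulation factor F10 (chromosome 8, 13037308 to 13056676) to 120 ± 49.1 from 51.8 ± 22.6 (1.20 ± 0.10; adjusted p = 0.000233 by the same edgeR test with Benjamini-Hochberg adjustment), and the actin-capping protein Capg to 150 ± 40.7 from 71.0 ± 29.9 CPM (1.09 ± 0.10). The glutathione transferase Mgst1 (1.21), the fatty acid receptor Gpr84 (1.12), the lectin Clec4e (1.1), the activating receptor Cd300lb (1.05), the protease inhibitor Slpi (0.98), the AP-1 factor Fosl2 (0.97) and Anxa3 (0.96) also rose. The adrenergic receptor Adrb1 (chromosome 19, 56722199 to 56733113) fell by 1.27, from 77.4 ± 13 to 33.8 ± 9.98 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000233). So did the adaptor Scimp (by 1.23), Plxdc2 (by 1.22), the semaphorin receptor Plxna4 (by 1.09), Galnt12 (by 1.08), Prss30 (by 1.02), Rtn1 (by 0.96), the transcription factor Runx3 (by 0.85) and Gkap1 (by 0.83). In all, 144 of 10909 genes passed, 78 higher and 66 lower, with 1414 at an unadjusted p under 0.05 and 133 by DESeq2.

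By group, monocyte and recruitment genes were higher in sick kidneys in 16 of 18, with 5 rising over all genes and 10 adjusted over the list alone (camera adjusted p = 2.22e-14, adjusted p = 0.148 with an estimated correlation, fry 0.0405). Haptoglobin Hp (0.75), Lyz2 (0.64), S100a4 (0.71) and S100a6 (0.66) were among them. Lysosome and lipid-associated genes were higher in 23 of 29, with 5 rising over all genes and 9 rising and 1 falling adjusted over the list alone (camera adjusted p = 9.06e-09, adjusted p = 0.129 with an estimated correlation, fry 0.0234). They included the fatty acid carrier Fabp5 (1.28), Gpnmb (1.43), the cathepsin inhibitor Cstb (0.72) and the lectin Lgals3 (0.49). Complement C3 and Cfb rose by 1.22 and 1.41, and 2 rose and 2 fell of 16 complement genes adjusted over the list alone (camera adjusted p = 0.0368, adjusted p = 0.506 with an estimated correlation). Oxidative phosphorylation genes were higher in 20 of 20, with 0 passing over all genes and 3 over the list alone (camera adjusted p = 0.000531), glycolysis genes in 17 of 19 (1 and 4, 0.000331), matrix genes in 14 of 19 (2 up and 1 down, 4 up and 2 down, 0.000531), and each of these 3 lists had an adjusted p of 0.148 with an estimated correlation. Plaur, the urokinase receptor of the matrix list, rose by 0.91, and the interleukin 1 antagonist Il1rn by 0.96, while the chemokine Cxcl16 fell by 0.48. Kidney-resident macrophage genes were lower in 15 of 20, 2 falling over all genes and 7 over the list alone, Cd81 by 0.48 and Itga9 by 0.57 (camera adjusted p = 0.000838, adjusted p = 0.422 with an estimated correlation). Antigen presentation genes were lower in 26 of 29, 0 over all genes and 8 over the list alone (7.23e-07, adjusted p = 0.506 with an estimated correlation). Neutrophil RNA was also higher, in 9 of 11 (camera adjusted p = 0.00305, adjusted p = 0.148 with an estimated correlation), and haemoglobin RNA was lower in 4 of 4 (0.0149, adjusted p = 0.506 with an estimated correlation), with no single gene past the threshold in either list. The count of 144 became 475 without B6.Sle1.Yaa hashtag 2 (young), 58 without B6.Sle1.Yaa hashtag 4, 66 without NZB/W hashtag 2, 65 without NZB/W hashtag 3 and 9 with doublets kept. Within 1 cluster per library 7 of 8384 genes passed, and of the 128 genes called over the class and tested there 5 passed and 115 had the same sign, with a median ratio of log2 differences of 0.523. Within these clusters Scimp (-0.75) and Plxdc2 (-1.17) were among those that passed, whereas Hmox1 had a log2 difference of -0.02, Plaur of -0.17, S100a6 of -0.18 and Lgals3 of -0.31.

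**Figure D3:**
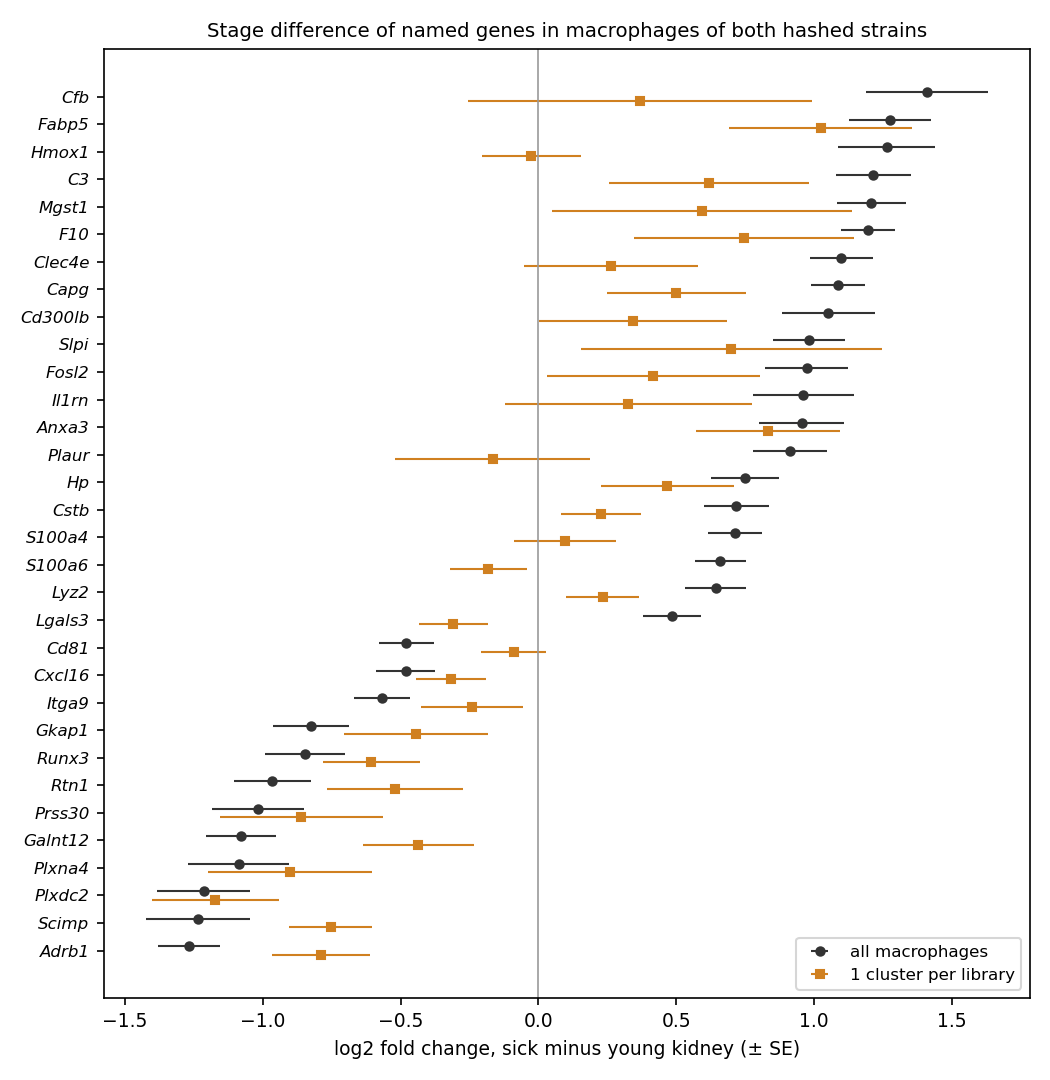
Log2 fold change (x axis) of named genes (y axis) in kidney macrophages of both hashed strains, sick minus young, with SE, over all macrophages (circles) and within 1 cluster per library (squares). Over all macrophages Hmox1 lies at 1.26, F10 at 1.20 and Adrb1 at -1.27, and within the clusters Hmox1 lies at -0.02.

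In NZB/W macrophages alone (2 sick hashtags against 1 young), 542 of 9672 genes passed, 256 higher and 286 lower (1438 at an unadjusted p under 0.05, 74 by DESeq2). The ectoenzyme Cd38 rose to 81.5 ± 39.6 from 9.11 CPM (log2 difference 3.20 ± 0.27; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.3e-17), and Pla2g7, a platelet-activating factor hydrolase, to 416 ± 68.6 from 89.9 CPM (2.21 ± 0.19). The lysozyme Lyz1 (3.48), complement C4b (2.79), the Fc receptor-like genes Fcrls (2.43) and Fcrl5 (2.02), the prostaglandin receptor Ptger2 (2.29), Apoc1 (2.22), Sirpb1c (2.21) and the chemokine Ccl8 (1.91) also rose, though Lyz1 had a log2 difference of -0.71 with hashtags called by the top share. The lectin Mgl2 fell by 2.73, from 812 to 123 ± 15.6 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.2e-50). The matrix proteases Mmp13 and Mmp12 fell by 2.63 and 1.87, Tspan7 by 3.61, Hs3st1 by 2.51 and Siglech by 2.23. Antigen presentation genes were lower in 29 of 29, 15 falling over all genes and 21 over the list alone (camera adjusted p = 4.89e-21, adjusted p = 0.741 with an estimated correlation), and the interferon-gamma targets Cxcl9, Cxcl10 and Gbp2 fell by 1.86, 1.23 and 1.11. Interferon-stimulated genes were lower in 23 of 28 (2 falling over all genes, 3 over the list alone, camera adjusted p = 0.000135, adjusted p = 0.741 with an estimated correlation). Monocyte genes rose in 10 of 16 over all genes and over the list alone (Ccr2 by 1.22, Cd44 by 0.94, Hp by 0.90, camera adjusted p = 8.84e-12, adjusted p = 0.741 with an estimated correlation). Lysosome genes rose in 9 and fell in 1 of 27 (13 and 2 over the list alone, camera adjusted p = 1.45e-08, adjusted p = 0.741 with an estimated correlation), with Ctsd up by 1.61, Ctsl by 1.45 and Plin2 by 1.32 and Cd36 down (-1.25). Complement rose in 5 of 13 (6 over the list alone, 2.91e-08), with Cfp up by 1.70, Cfb by 1.72 and Itgam by 1.49, and scavenger receptors in 5 of 19 (6 over the list alone, 2.75e-05), each with adjusted p = 0.741 with an estimated correlation. Neutrophil RNA rose in 1 of 9 genes and was higher in 8 (0.0206, adjusted p = 0.741 with an estimated correlation). Hmox1 rose by 1.24 and the efferocytosis receptor Mertk by 1.64.

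Different clusters held most of these NZB/W macrophages at the 2 stages. In the young hashtag 69.8% lay in a cluster led by Mmp13, Mgl2, Scimp and Mmp12, against 3.2% and 7.3% in the sick hashtags. In the sick hashtags 48.4% and 46.2% lay in a cluster led by Ms4a7, C1qa, Apoe and Cxcl13 (10.9% in young), and 38.5% and 23.8% in a cluster led by Cxcl13, Ccl8, Ccl7 and Vcam1 (3.6% in young). Genes such as Mgl2 and Ccl8 thus helped to define the clusters. Mgl2 is also on the list of cDC2 markers used to name clusters. Whether the cluster led by Mmp13 held dendritic cells was not tested, nor were antigen presentation genes as a list within a cluster. Within the cluster led by Ms4a7 alone, 13 of 6277 genes passed, 3 higher and 10 lower. Of the 450 genes called over the class and tested there, 11 passed and 385 kept their sign, with a median ratio of log2 differences of 0.551. Cd38 (3.99) and Sirpb1c (1.62) rose within it, Mgl2 (-1.62), Cxcl9 (-2.04) and Cd36 (-1.26) fell, while Lyz1 (1.91), Fcrl5 (0.84), Pla2g7 (0.94) and Fcrls (0.03) did not pass. Ccl8, which rose over the class, fell within it by 1.91 (adjusted p = 0.0347 by the same edgeR test).

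In B6.Sle1.Yaa macrophages (2 sick hashtags against 1 young), 307 of 11520 genes passed, 162 higher and 145 lower (1522 at an unadjusted p under 0.05, 81 by DESeq2). F10 rose to 166 ± 2.14 from 69.4 CPM (log2 difference 1.26 ± 0.10; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.1e-07) and Hmox1 to 323 ± 53.2 from 134 CPM. Gpnmb (1.47), the heparanase Hpse (1.34), Nrp2 (1.30), Gpr84 (1.27), Mgst1 (1.26), C3 (1.14), the neutrophil chemokine Cxcl2 (1.04) and Plaur (0.97) rose. Retnla, a marker of alternative activation, fell to 0.140 ± 0.197 from 34.9 CPM. The intermediate filament gene Nes fell by 1.69, the stress genes Ddit4 and Fkbp5, both glucocorticoid targets, by 1.62 and 1.46, Adrb1 by 1.43, Ifi44 by 1.14 and Fabp4 by 1.06. Monocyte genes rose in 8 and fell in 1 of 18 (11 and 1 over the list alone, camera adjusted p = 5.0e-14, adjusted p = 0.56 with an estimated correlation), among them S100a4 (0.63), S100a6 (0.66) and Plac8 (0.67). Lysosome genes rose in 8 and fell in 2 of 29 (11 and 2 over the list alone, camera adjusted p = 1.52e-09, adjusted p = 0.56 with an estimated correlation), among them Cstb (0.97) and Ctsd (0.67). Kidney-resident genes fell in 8 of 20 (10 over the list alone, camera adjusted p = 2.57e-07, adjusted p = 0.56 with an estimated correlation), with Cd72 down by 0.79, Cd81 by 0.47 and C1qa by 0.37. Oxidative phosphorylation genes were higher in 20 of 20 (1 over all genes, 5 over the list alone, 0.00016) and glycolysis genes in 18 of 20 (1 and 6, 5.14e-05), both with adjusted p = 0.56 with an estimated correlation. The mix of clusters differed less here: the largest cluster held 34.5% and 32.5% of sick and 34.3% of young macrophages. Within it 66 of 9521 genes passed. Of the 281 called over the class and tested there, 36 passed and 245 kept their sign, with a median ratio of 0.617, while Hmox1, S100a6 and S100a4 had log2 differences of -0.04, -0.07 and -0.10 there. The class count of 307 became 753 with the mixture rule for hashtags, 517 without the filter, 486 with the mitochondrial limit at 20%, 485 with doublets kept and 99 at Leiden resolution 2.

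Classical monocytes of sick NZB/W kidneys differed from those of the young hashtag in 88 of 6158 genes, 43 higher and 45 lower (608 at an unadjusted p under 0.05, 13 by DESeq2). The chemokine Ccl4 rose to 813 ± 14.4 from 86.9 CPM (log2 difference 3.23 ± 0.33; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.5e-18). The formyl peptide receptor Fpr1 (2.25), the fatty acid carrier Fabp4 (2.15) and Il1b (1.06) rose, and so did Slpi (1.81), named after its values were seen. Ly6c2, the surface marker of classical monocytes, fell by 2.70, from 718 to 116 ± 28.7 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.8e-29). Thrombospondin Thbs1 fell by 2.25, the lectin Clec10a by 2.94, F13a1 by 1.40, H2-DMb1 by 1.39, Fn1 by 1.24 and Cd74 by 1.00. Antigen presentation genes fell in 6 of 22 (8 over the list alone, camera adjusted p = 1.63e-11) and monocyte genes rose in 1 and fell in 4 of 17 (2 and 6 over the list alone, 2.83e-07, fry 0.0357), while lysosome genes rose in 3 and fell in 1 of 27 (7 and 1 over the list alone, 1.52e-06). Each of these had an adjusted p of 0.828 with an estimated correlation. The young hashtag gave only 51 of these cells, and the count of 88 became 34 with doublets kept and 50 without the filter.

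Over both strains (3 sick and 2 young hashtags), 10 of 8347 genes passed in classical monocytes, and each of them rose (390 at an unadjusted p under 0.05, 3 by DESeq2). The cystine transporter Slc7a11 rose to 34.6 ± 6.41 from 4.88 ± 0.978 CPM (log2 difference 2.79 ± 0.48; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0145). Il1b rose to 520 ± 212 from 242 ± 74.7 CPM and its antagonist Il1rn to 159 ± 44.4 from 52.9 ± 27.5 CPM. The endotoxin co-receptor Cd14 (1.17), the lectins Clec4d (1.38) and Clec4e (1.00), the transglutaminase Tgm2 (1.40), Slpi (1.28) and the platelet-activating factor receptor Ptafr (1.23) rose, as did Marcksl1 (1.06), whose groups overlapped and which was named after its values were seen. Cytokine genes were higher in 16 of 23, with 2 rising over all genes and 4 over the list alone (camera adjusted p = 0.000252, adjusted p = 0.729 with an estimated correlation). The count of 10 became 89 without B6.Sle1.Yaa hashtag 2 (young), 42 higher and 47 lower, 91 without B6.Sle1.Yaa hashtag 4, 42 higher and 49 lower, 52 without NZB/W hashtag 1 (young), 37 higher and 15 lower, and 0 without NZB/W hashtag 3. In B6.Sle1.Yaa alone only sick hashtag 4 and young hashtag 2 reached the minimum, so no test was made. Thbs1 stood at 159 CPM (140 to 181) in sick against 5.53 (2.39 to 10.9) in young cells, Ccl2 at 141 against 24.2, Cxcl2 at 227 against 47.7, Hmox1 at 428 against 102 and Il1rn at 115 against 33.2 CPM. S100a8 stood at 99.1 (83.8 to 117) against 494 (458 to 532), S100a9 at 81.7 against 243, Wfdc21 at 22.8 against 87.0, Fabp4 at 44.2 against 131 and Cd300e at 31.5 against 80.8 CPM. The cytokine list had a median log2 ratio of 0.56 (percentile 100 of random lists) and neutrophil RNA one of -0.87 (percentile 0.0).

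Shares of cell classes shifted with stage in both hashed libraries, but 2 sick hashtags against 1 young allow no exact permutation p below 0.333, so no shift can pass (adjusted p = 0.917 or higher). In NZB/W, nonclassical monocytes were 5.95% of young kidney cells (Wilson interval 4.86 to 7.26) and 31.5 ± 14.8% of sick kidney cells, macrophages 58.6% and 44.1 ± 7.49%, classical monocytes 3.41% and 15.1 ± 10.4%, and cDC2 21.0% and 3.69 ± 1.05%. In B6.Sle1.Yaa, nonclassical monocytes were 50.4% of young kidney cells (Wilson interval 48.5 to 52.3) and 17.5 ± 2.26% of sick kidney cells, macrophages 28.7% and 58.3 ± 9.82%, and cDC2 3.34% and 7.09 ± 2.16%. The shift of nonclassical monocytes, 25.6 points in NZB/W and -32.9 in B6.Sle1.Yaa, was 8.39 and -31.4 with the mitochondrial limit at 20%, and 2.32 and -22.1 with doublets kept. About 51.8% of NZB/W and 37.8% of B6.Sle1.Yaa barcodes carried no hashtag call and are outside these shares.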

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

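Of the tests in this part, those of the NZW/BXSB 3 and 4 libraries, of crossed hashtag names, of cell depth, of hashtag background for part of a shift and of strain variants without sex-linked genes were chosen after the result was seen, as were the comparison of kidney with blood and the stage comparison in nonclassical monocytes.

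The effect of stage differed between the hashed strains, by an interaction term in the same edgeR quasi-likelihood test, in 92 of 10909 macrophage genes and 35 of 8630 nonclassical monocyte genes. As the log2 difference by stage in NZB/W minus that in B6.Sle1.Yaa, macrophages had Fkbp5 at 2.25, Pla2g7 at 2.09, Cxcl9 at -2.08 and Sema4a at -1.72. Nonclassical monocytes had Serpinb10 at -4.08, Lyz2 at -1.52, Pecam1 at 2.51 and Ccnd2 at 2.10. In classical monocytes the term passed in 61 of 8347 genes, but B6.Sle1.Yaa had 1 sick and 1 young sum there, so the spread came from the NZB/W sick pair alone and no gene is named. The mix of clusters within macrophages moved with stage in NZB/W far more than in B6.Sle1.Yaa, so some of these differences may lie in the mix. Within 1 cluster Pla2g7 rose by 0.94 in NZB/W and did not pass, against 2.21 over the class, while Cxcl9 fell by 2.04 and passed. Nonclassical monocytes of NZB/W also changed clusters with stage, so the mix may play a part for them too. The cluster led by Ace held 77.5% of the young cells against 31.7% and 18.2% of the sick kidney cells. Each strain is 1 library, so strain and library are 1 factor here. Each also gave only 1 young hashtag, so in every class the spread comes from the sick hashtags alone.

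In 3 classes the share moved in opposite directions with stage, every sick hashtag of 1 strain up and of the other down; the difference itself was not tested. Not every class did so, since B cells fell in every sick hashtag of both strains. The share of macrophages moved by -14.5 points in NZB/W and 29.6 in B6.Sle1.Yaa, and that of cDC2 by -17.4 and 3.75 points. The share of nonclassical monocytes moved by 25.6 points in NZB/W and by -32.9 in B6.Sle1.Yaa, but by only 8.39 in NZB/W with the mitochondrial limit at 20% and 2.32 with doublets kept (-31.4 and -22.1 in B6.Sle1.Yaa). For it 3 technical explanations were weighed. Crossed hashtag names in 1 library would turn the monocyte list in macrophages opposite ways, provided that the list truly moves alike in both strains. Its median log2 difference was positive in both strains, at 0.595 in the smaller. Whether the strains respond alike is itself in question, so the list cannot decide on crossed names. Background counts of the young B6.Sle1.Yaa hashtag would thin out nonclassical monocytes among its strongest cells. Among the 652 cells with the highest counts of that hashtag 250 (38.3%) were of this class, -12.1 points from the 50.4% over all its cells, but more than 10 points above either sick hashtag. Background may thus account for part of the B6.Sle1.Yaa shift of -32.9 points and not for all of it. Depth would need young and sick cells to differ in opposite ways. Over all cells the young were deeper in both strains, by 1.30 and 1.43 times. Among nonclassical monocytes, however, the median UMIs did go opposite ways. They were 2557 in young against 3001 and 2825 in sick NZB/W hashtags, and 8656 against 6601 and 6496 in B6.Sle1.Yaa. The ratio over all cells thus cannot decide on depth. The tables argue against background as the whole cause. Crossed names stay open, as do depth and the cell filters, on which the size in NZB/W depends. So do strain, sex, age and the selection of cells in each pool, untested. A biological difference between the strains is no more than a hypothesis.

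Haemoglobin RNA in NZW/BXSB 4 stood far from the other Tlr7-overexpression libraries, at 15960 CPM, and Xist in B6.Sle1.Yaa stood at 0 CPM where the NZW/BXSB libraries had 1 to 4 counts. Among 23 groups of 4 values searched, chance marks about 5 per 100. Between kidney and blood, a contrast outside the planned comparisons, 399 genes passed in NZB/W nonclassical monocytes by the edgeR quasi-likelihood test. This count fell to 49 with DESeq2, 31 with the mitochondrial limit at 20% and 8 with doublets kept.

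The libraries NZW/BXSB 3 and 4 held little kidney RNA, and both another tissue, or a wrong label, and a bead selection that removed kidney cells were weighed. The summed tubule list was the lowest of the 7 libraries in NZW/BXSB 3 (705 CPM), but at 912 CPM NZW/BXSB 4 lay within the range of the other 5 (873 to 1781 CPM, the higher of the 2 at 1.05 times the lowest). A sum is carried by its most abundant members, and Napsa, made by immune cells too, gave 489.8 of these CPM in NZW/BXSB 3 and 346 in NZW/BXSB 4, so the sum says little on the other genes. Gene by gene, the median of the higher of the 2 over the lowest of the other 5 was 0.0671, with Fxyd2 and Miox at 0.0145 and 0.0203. The test took bead selection to leave the macrophages that remain alike, which was not checked, since the beads of each library are not given. Those of NZW/BXSB 3 lay -2.24 (log2) from the next library in kidney-resident genes, and myeloid precursor genes summed there to 13.3 times the highest of the other 5. For NZW/BXSB 4 the precursor sum was only 1.81 times that value (118.5 against 65.5 CPM) and no cluster was named macrophage, so there bead selection cannot be told apart from another tissue. For NZW/BXSB 3 cells from another tissue, far less tissue RNA at dissociation or beads that took other macrophages could give these values, which cannot be told from the counts. The labels name kidney.

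The H2-Q genes that part MRL/lpr from NZW/BXSB macrophages were weighed against reads shared between copies. The test took such reads only to move between copies, which would leave their sum unchanged. The sum of 6 H2-Q genes differed by 1.81 on the log2 scale (5072 and 5095 against 1204 and 1693 CPM). Shared reads may also go uncounted, or to copies outside these 6 genes, so the sum cannot decide on them. A variant of the strains, in the genes or their regulation, would show in other cells too. Of the 15 genes past the threshold that are not sex-linked, 12 could be compared in T cells, 12 had the same sign, and the median ratio of the T cell to the macrophage difference was 0.778. H2-Q4, H2-Q1 and H2-Q6 stood at 0.699, 0.951 and 1.38, but Art2b at 0.092 and Serpina3f at 0.395. A strain variant may thus account for the H2-Q differences, including variants that change how reads map to the reference, less so for Art2b and Serpina3f. Effects of disease or sex on these genes were not tested. For the 6 genes past the threshold by model type in macrophages, the 10 splits of 3 against 3 are too few for a share under 0.05, with 6 genes in the real split, 2 in the highest other and 1 split as large.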

How the results depend on the processing

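The alternatives with kidney or sick hashtags only, clusters of at least 1500 median UMIs, NZW/BXSB 3 and 4 left out, the mixture rule, 1 cluster per library and the minimum of 50 cells for Tlr7 were chosen after the data were seen, as were the stage comparison in nonclassical monocytes and that of kidney with blood. Of 2458 values of tested named genes under alternatives, 1894 kept their direction and side of the threshold, 505 lost the call, 43 gained it and 16 turned; 29 of the 166 named calls held in every alternative run. For the 31 genes named without a test, 97 of 113 values stayed within the counting interval and the other 16 kept their direction. No paired analysis was possible because the labels give no number shared between groups (each hashed strain is 1 library, without one), and single-strain stage fits lose their residual degrees of freedom when a hashtag is left out. Where no value shows it, the cause was not tested.

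Model type in macrophages (6 genes) gave 591 with DESeq2, 53 unfiltered, 3 without the covariate, 13 per strain, 0 with strains summed, 3 in deep clusters, 3 without NZW/BXSB 3 and 4, and 0 to 23 with each library left out. Classical monocytes (0) gave 83 with DESeq2, 122 unfiltered, 29 at 20% mitochondrial UMIs and 5 at resolution 2. Nonclassical monocytes (23) gave 304, 131, 109 and 15 under these 4, 8 without the covariate, 122 per strain, 0 with strains summed, 13 with sick hashtags only, 0 without NZW/BXSB 3 and 4, and 11 to 117 with each library left out. At resolution 2, cDC2 and MRL/lpr against NZW/BXSB classical monocytes reached enough sums for the edgeR test and gave 0 of 9105 and 0 of 9338 genes (721 and 298 at an unadjusted p under 0.05; DESeq2 was not run there). MRL/lpr against NZW/BXSB macrophages (18) gave 461 with DESeq2, 1649 unfiltered and 15 to 379 with each library left out.

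By stage, NZB/W macrophages (542) gave 74 with DESeq2, 215 by top hashtag share and 13 in 1 cluster; NZB/W classical monocytes (88) gave 13 with DESeq2, 50 unfiltered and 34 with doublets kept. B6.Sle1.Yaa macrophages (307) gave 81 with DESeq2, 517 unfiltered, 486 at 20% mitochondrial UMIs, 485 with doublets kept, 99 at resolution 2, 753 by the mixture rule and 66 in 1 cluster; classical monocytes, untested in the design, gave 125 with doublets kept and 110 by top share. Pooled macrophages (144) gave 545 unfiltered, 9 with doublets kept, 51 at resolution 2, 351 by top share, 317 by mixture, 7 in 1 cluster and 58 to 475 with each hashtag left out. Pooled classical monocytes (10) gave 3 with DESeq2, 41 unfiltered, 16 at 20%, 4 with doublets kept, 31 at resolution 2, 27 by mixture and 0 to 91 with each hashtag left out. Pooled nonclassical monocytes (9, 6 up and 3 down, or 6 and 6 with RLE) gave 14 with DESeq2, 141 unfiltered, 39 at 20% (11 up, 28 down), 52 with doublets kept (21 and 31), 74 at resolution 2 (33 and 41), 2 at the stricter quantile, 45 by top share (19 and 26), 18 by mixture, 1 in 1 cluster and 1 to 150 with each hashtag left out. Kidney against blood (399) gave 49 with DESeq2, 31 at 20%, 8 with doublets kept, 149 by top share and 1 in 1 cluster.

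Of the list calls by camera, 37 of 61 by model type became 0 with an estimated correlation and 3 by fry, and 45 of 120 by stage became 0 and 5. In simulated counts with 1 list raised, camera called it in 11 of 11 comparisons but with an estimated correlation in only 2 (adjusted p = 0.0377 and 0.0068). The check with an estimated correlation can thus miss a list that moves. The simulated genes varied independently of each other, so the simulation cannot show how many camera calls in the real data come from correlated genes. The nonclassical monocyte shift was 8.39 points in NZB/W at 20% mitochondrial UMIs and 2.32 with doublets kept, and -22.1 in B6.Sle1.Yaa with doublets kept and -29.1 by mixture. The log2 ratio of Tlr7 by model type was 0.23 in classical monocytes with the 20 cells of NZW/BXSB 4, and 0.055 over libraries with at least 50. Turned signs were Tlr7 by model type in classical monocytes (-0.18 as tested, 0.616 at 20%, 0.0438 with doublets kept, 0.0487 at resolution 2, 0.0864 without the covariate and with strains summed), Lyz1 in NZB/W macrophages (-0.71 by top share), AY036118 in nonclassical monocytes (-0.0938 to 1.21 with each hashtag left out) and, in 1 cluster, Ccl8 in NZB/W (-1.91), Hmox1 (-0.0731 in NZB/W, -0.0357 in B6.Sle1.Yaa, -0.0249 pooled), S100a6 and S100a4 in B6.Sle1.Yaa (-0.0689 and -0.0955), and pooled Lgals3, S100a6 and Plaur (-0.309, -0.182 and -0.166).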

Other observations

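The comparison of kidney with blood, the stage comparison in nonclassical monocytes and the genes named for them were chosen after the data were seen.

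Nonclassical monocytes of sick NZB/W mice differed between kidney (2 hashtags) and blood (1 hashtag) in 399 of 8315 genes by the edgeR quasi-likelihood test, 226 higher and 173 lower in kidney. Blood is a single hashtag, so the p-values rest on the spread between the 2 kidney hashtags alone. The count fell to 149 by top hashtag share, 49 with DESeq2, 31 with the mitochondrial limit at 20% and 8 with doublets kept. The vasoconstrictor peptide Edn1 (log2 difference 2.94), the membrane protease Mmp14 (2.69), the proteoglycan Sdc4 (2.46), the acute phase protein Saa3 (2.07), the chemokine Ccl4 (2.03), Il1rn (1.94), the transcription factor Maf (1.65), the chemokine receptor Ccr2 (1.56), Ms4a6d (1.51) and Lpl (1.47) rose in kidney. Tppp3 fell by 1.92 (750.7 in blood against 202 ± 63.8 CPM in kidney), the transcriptional repressor Hes1 by 1.38, and Ace, a marker of the class, by 1.25. Kidney-resident macrophage genes rose in 13 of 20, over all genes and over the list alone (camera adjusted p = 6.29e-20, adjusted p = 0.591 with an estimated correlation), and cytokines rose in 7 and fell in 1 of 23 (12 and 1 over the list alone). Interferon-stimulated genes rose in 7 of 24 (8 over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.743 with an estimated correlation). Haemoglobin RNA rose in 2 of 3 genes (camera adjusted p = 3.68e-07, not called with an estimated correlation), Hba-a1 by 3.76. This rested on 1 of the 2 kidney hashtags (Hba-a1 at 271 and 8.23 CPM against 9.26 in blood). Over all cells haemoglobin RNA summed to more in blood (929.9 CPM) than in the kidney hashtags (334.3 and 37.8 CPM). Different clusters held most of the class: 68.3% and 81.8% of the kidney cells lay in a cluster led by Clec4e, Fabp4, Edn1 and Lpl, and 88.5% of the blood cells in one led by Ace, Pglyrp1, Tppp3 and Ear2. Within the second cluster 1 of 4041 genes passed, Ccr2 (1.34), and of 313 genes called over the class and tested there 306 kept their sign.

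By stage, nonclassical monocytes of both strains (4 sick and 2 young hashtags) differed in 9 of 8630 genes by the edgeR quasi-likelihood test. The formyl peptide receptor Fpr1 (1.03), the chemokine-binding receptor Ccrl2 (1.1), the NF-kappaB signalling gene Malt1 (0.90), Tnfaip2 (0.81), Marcksl1 (0.93) and AY036118 (1.08) rose in sick kidneys, and the cytoskeletal genes Tagln2, Syne1 and Dst fell by 1.15, 1.51 and 1.45. Cytokine genes were higher in 19 of 22, with 0 passing over all genes and 8 over the list alone (camera adjusted p = 1.36e-14, adjusted p = 0.0599 with an estimated correlation, fry 0.031). AY036118 had a log2 difference of -0.0938 without B6.Sle1.Yaa hashtag 2. In NZB/W, 77.5% of the young cells lay in the cluster led by Ace, and 68.3% and 81.8% of the sick kidney cells in that led by Clec4e and Fabp4. In B6.Sle1.Yaa a cluster led by Fcgr4, Fabp4 and Fcrl5 held 37.2% of the young cells against 6.4% and 17.4% of the sick kidney cells. Within 1 cluster per library 1 of 5176 genes passed, and of the 7 genes called over the class and tested there 0 passed and 7 kept their sign, with a median ratio of log2 differences of 0.754. The count of 9 became 3 without B6.Sle1.Yaa hashtag 1, 26 without hashtag 2, 1 without hashtag 4, 150 without NZB/W hashtag 1 (64 up, 86 down) and 5 without hashtag 2 or 3 (1 up, 4 down).

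The B6.Sle1.Yaa blood hashtag gave 193 kept cells, of which 44 fell in macrophage clusters (22.8%, Wilson interval 17.4 to 29.2) and 28 in nonclassical monocyte clusters (14.5%, 10.2 to 20.2), whereas 25 of 1056 NZB/W blood cells fell in macrophage clusters (2.37%, 1.61 to 3.47). Whether the B6.Sle1.Yaa cells came from blood or were called from hashtag background was not tested. NZW/BXSB 2 held 21711 barcodes although up to 10000 cells per channel were loaded according to the protocol.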
